A study of Homo sapiens with 6 samples.

How the data were processed

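Methylated RNA immunoprecipitation sequencing (MeRIP-seq) was performed on wild-type HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. In MeRIP-seq, fragments of RNA that carry N6-methyladenosine (m6A) are pulled down with an antibody and sequenced beside the RNA that was not pulled down, the input. The 6 samples were the immunoprecipitated (IP) and input libraries of 3 repeats of the same experiment, named MeRIP 1, MeRIP 2 and MeRIP 3 in the labels. Total RNA was the starting material, ribosomal RNA was removed from IP and input, and libraries were sequenced as 150 bp paired-end reads, per the labels' protocols.

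Per the submitters' processing notes, cutadapt 1.9.3 and HISAT2 2.0.4 were used and the genome build was hg19. Names of the peaks carry the word MACS, a peak caller, whose version and settings are not given in the sources used here. The authors deposited 1 peak list for each repeat, which the labels tie to both the IP and the input of that repeat, so peaks were called per repeat and not on pooled repeats. The deposited lists give each peak a start, an end, a strand and a score. The score deposited by the authors for each peak ran from 50 up to a value of 3100 shared by many peaks, which is the form of a MACS score of minus 10 times the log10 of a p-value. No header states this, so the scale is read from the values. On that scale a ratio or log2 difference of scores compares logs of p-values. Scores of 3100 or more were treated as a ceiling, and scores above it were set to it before taking log2. The score is the authors' own value per peak, so it depends on coverage in IP and input and on the width of the peak as well as on methylation. Peak numbers in the names ran up to 96698, 74706 and 75015, while 22.0%, 26.6% and 26.7% as many peaks were listed, so the lists hold part of the peaks called. The file names speak of mRNA. The rule by which the authors chose or trimmed peaks is not given in the sources used here. Read depth of the libraries is unknown from peak lists, so no interval on a read count is given.

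Peaks of the 3 lists that shared at least 1 bp on the same strand were merged into regions, and each region was scored by the lists with a peak in it. Chance overlap was measured by moving every peak by a random distance of 5 to 50 kb on its own chromosome and strand, in 100 draws. This chance level does not keep peaks in exons, so it is lower than one that would. A stricter chance level, chosen after seeing the data, drew each list's number of regions at random from all called regions, in 100 draws. Its pool holds only regions called in at least 1 of these same lists. A large overlap is thus built in, and the ratio to this level does not give the size of agreement beyond chance. Scores were compared between lists by Spearman and Pearson correlation of log2 scores across regions, taking the highest score per region and list. Regions and peaks are not independent replicates. Median log2 scores of peaks in all 3 lists and of peaks in 1 list alone were compared within each list by a two-sided permutation test with 100000 draws, adjusted by Benjamini-Hochberg over the 3 lists (2000 draws for alternatives). Shares carry 95% Wilson intervals, which cover counting error only. Over the 3 lists alone a sign test cannot give a two-sided p under 0.25. Edges of peaks were compared to the base in regions with 1 peak in each list, and were called upstream or downstream along the deposited strand. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. On simulated lists of 12000 regions, all 6000 planted in 3 lists and all 3000 planted in 1 list were recovered. A planted log2 score difference of 2 was estimated as 1.99. The planted peaks lay far apart, with small shifts and no lowest score, so this checks the code and not the real lists. In a separate simulation of 400 values with no planted difference, 7% of 100 tests had p under 0.05.

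The tests, alternatives and 16 gene lists were fixed before the data were examined, apart from those named as chosen later. That plan had no entry for peak edges and their width classes, score bins, score spreads, clusters or chromosomes. Intervals given for these are descriptive. The lists carry no gene names, and no hg19 genome or annotation was used here. The gene table at hand is of GRCh38.p14, another build, and its coordinates were not used. The planned assignment of peaks to genes, the 16 gene lists, the rule for named genes (METTL16, SF3B4, MAT2A, members of the lists and the genes with the highest scores or most regions), transcript location, long internal exons and sequence motifs were therefore not analysed here. Regions are named by position instead, by rules chosen after the values were seen: the widest at the score ceiling, the largest clusters and the largest score differences. Coordinates are hg19, counted from 1.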

Results

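Peaks of m6A signal in the RNA of wild-type HEK293T cells were called in 3 repeats of MeRIP-seq, each an IP library set against its own input. m6A is the most abundant internal modification of mRNA and is added mostly by METTL3 with METTL14, while METTL16 methylates a separate set of RNAs. The series concerns RNA methylated by METTL16 and its recognition by SF3B4, a subunit of the SF3b splicing complex. Per the series design text, the submitters set the repeats against each other to exclude non-specific reads. The deposited lists still hold regions found in 1 list alone. Recurrence between lists was not tested here as a measure of specificity. MeRIP 1 gave 21286 peaks, MeRIP 2 gave 19851 and MeRIP 3 gave 20010, with a mean of 20382 ± 787 peaks (SD, n = 3 lists). The peaks covered 15.7 ± 0.230 Mb of the genome per list, with a median width of 429.5 ± 13.6 bp. Of all peaks, 51.4 ± 0.161% lay on the plus strand. The labels do not say whether the repeats came from separate cultures, so spreads between lists may be technical.

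The first question was which peak regions were found in every repeat. Most were: of 25737 regions with a peak in any list, 15265 (59.3%) had a peak in all 3 lists, 4595 (17.9%) in 2 lists and 5877 (22.8%) in 1 list. The regions in all 3 lists covered 14.1 Mb. Counted by peaks, 75.4 ± 2.80% of a list's peaks lay in regions of all 3 lists and 9.54 ± 2.71% were found in that list alone. MeRIP 1 had 2696 regions of its own, against 1559 in MeRIP 2 and 1622 in MeRIP 3. Peaks moved at random by 5 to 50 kb gave 151.1 ± 12.8 regions in all 3 lists and at most 180 in 100 draws. The observed number was above every draw (one-sided permutation p = 0.0099, the smallest that 100 draws can give). Moved peaks were not kept in exons, so this level is low and does not give the size of agreement beyond chance. Drawing each list at random from the called regions gave 12581 ± 38.3 regions in all 3 lists. The observed number was 1.21 times that mean and above every draw (one-sided permutation p = 0.0099). That pool holds only regions called in these same lists, so a large overlap is built in and the ratio does not size the agreement.

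**Figure D1:**
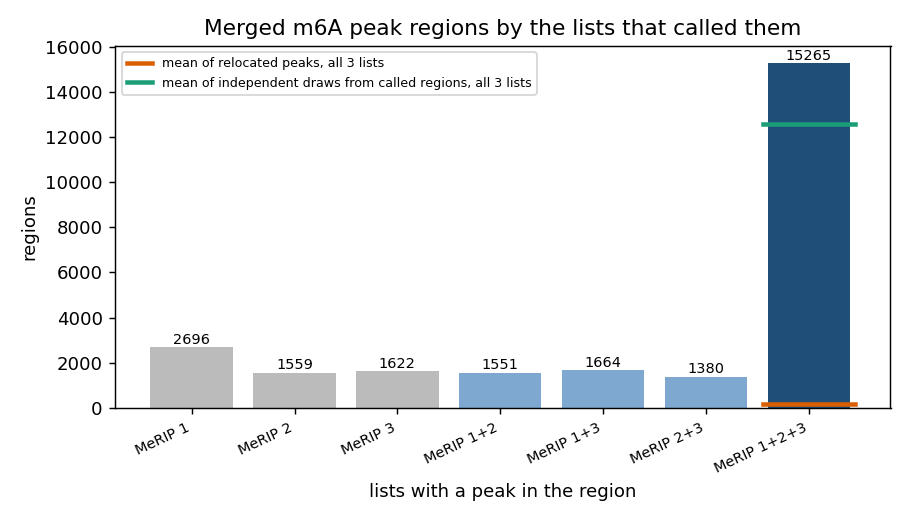
Number of merged m6A peak regions (y axis) for each combination of lists with a peak in the region (x axis: MeRIP 1, 2 and 3). The bar of 15265 regions in all 3 lists stands above the mean of relocated peaks (151.1) and of independent draws from the called regions (12581), drawn as lines. Relocated peaks were not kept in exons, and the independent draws came from regions called in these same lists.

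Between any pair of lists, most peaks had a partner. Of the peaks of MeRIP 2, 85.2% overlapped a peak of MeRIP 1 and 84.3% one of MeRIP 3. For MeRIP 3 the shares were 85.0% in MeRIP 1 and 83.5% in MeRIP 2. The larger list of MeRIP 1 had 79.5% of its peaks in MeRIP 2 and 80.0% in MeRIP 3. The mean over the 6 directions was 82.9%. Relocated peaks, which were not kept in exons, gave a mean of 3.37% and at most 3.79%.

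The next comparison was between the strength of regions found every time and that of regions found once. Peaks in regions of all 3 lists were stronger in each list. The median score was 781 for such peaks of MeRIP 1 against 90.9 for peaks of MeRIP 1 alone, 668 against 85.8 in MeRIP 2, and 739 against 84.3 in MeRIP 3. The difference of medians was 3.07 ± 0.0914 on the log2 scale (SD, n = 3 lists) and was positive in 3 of 3 lists (two-sided permutation test over peaks, adjusted p = 1e-05 in each list, the smallest that 100000 draws can give). The lists hold no score under 50, so a peak is found in all 3 lists only where it passes that limit in each, and a higher score of such peaks is expected wherever scores are correlated between lists. The score is read as the log of a p-value, so ratios of scores, here and below, are not folds of methylation. Peaks found in all 3 lists were also wider, with medians of 527, 530 and 531 bp against 204.5, 214 and 209 bp for peaks of 1 list alone. Of the peaks of 1 list alone, 80.6 ± 0.918% had a score under 200.

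Recurrence was higher among peaks at the score ceiling than among the weakest peaks in every list. Because the lists hold no score under 50, such a rise with score is expected wherever scores are correlated between lists. Of peaks with scores from 50 to below 75, 30.7 ± 4.16% lay in regions of all 3 lists and 35.9 ± 8.08% were found in 1 list alone (SD, n = 3 lists). From 200 to below 300 these shares were 76.2 ± 4.22% and 6.20 ± 3.15%, and from 1000 to below 2000 they were 93.7 ± 1.45% and 1.98 ± 1.01%. Of the 10925 peaks at the score ceiling of 3100 or more, 96.0 ± 0.320% lay in regions of all 3 lists and 1.34 ± 0.187% in 1 list alone. In the lowest bin MeRIP 1 had 45.1% of peaks to itself (95% Wilson interval 43.0 to 47.2%), above the 29.9% of MeRIP 2 (28.0 to 31.9%) and the 32.7% of MeRIP 3 (30.7 to 34.8%).

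**Figure D2:**
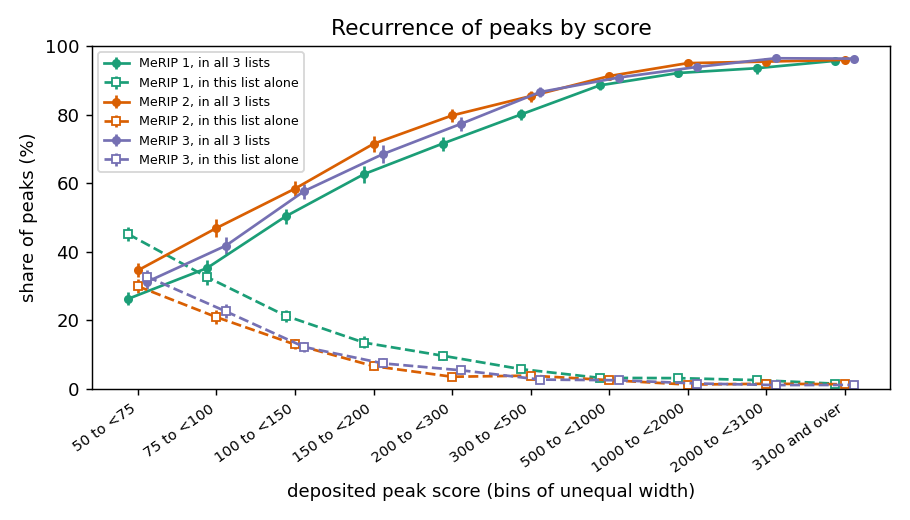
Share of peaks in percent (y axis) that lie in regions of all 3 lists (filled circles) or in 1 list alone (open squares), by bin of the deposited score (x axis), for each of the 3 lists. Bars are 95% Wilson intervals, and the share in all 3 lists goes from a mean of 30.7% in the lowest bin to 96.0% at the ceiling.

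Scores of shared regions were correlated between lists. Across regions, Spearman's rho was 0.89 between MeRIP 1 and MeRIP 2 (16816 regions), 0.89 between MeRIP 1 and MeRIP 3 (16929 regions) and 0.91 between MeRIP 2 and MeRIP 3 (16645 regions). Pearson's r of log2 scores was 0.88, 0.88 and 0.90. These are correlations across regions, which are not independent replicates, and they include regions tied at the ceiling. Among regions below the ceiling in both lists rho was 0.79, 0.78 and 0.82, and the SD of the log2 ratio of scores was 1.01, 1.04 and 0.94. The median log2 ratio was -0.15 for MeRIP 2 over MeRIP 1, -0.05 for MeRIP 3 over MeRIP 1 and 0.11 for MeRIP 3 over MeRIP 2. Of the 11131 regions below the ceiling in all 3 lists, 5834 (52.4%) had scores within 2-fold of one another and 179 (1.61%) had scores over 10-fold apart. The widest spread among these was on chromosome 19 at 44469956 to 44471752 on the plus strand, with a score of 62.3 in MeRIP 1, 1737 in MeRIP 2 and 2461 in MeRIP 3. The next was on chromosome 16 at 20745021 to 20748608 on the minus strand, with 63.2, 1436 and 2199. Both were chosen after their values were seen.

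At the strong end, 2888 regions (18.9% of those in all 3 lists) were at the ceiling in every list. Their median width was 1296.5 bp, against 421 bp for the other regions in all 3 lists. The widest was a region of 18173 bp on chromosome 11 at 62283374 to 62301546 on the minus strand, with the same start and end in all 3 lists. Another with identical edges spanned 8765 bp on chromosome 17 at 77906142 to 77914906, also on the minus strand. A region of 9638 bp on chromosome X at 153287264 to 153296901 on the minus strand was made of 2 peaks in each list, and a region of 9158 bp on chromosome 7 at 4801815 to 4810972 on the plus strand of 2, 1 and 2 peaks in MeRIP 1, 2 and 3. Across regions in all 3 lists, width and the lowest log2 score had a Spearman rho of 0.44.

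Most clusters of regions in all 3 lists held a single region. When regions on the same strand within 10 kb of one another were chained, 10843 clusters resulted, of which 8299 (76.5%) held a single region, 2531 held 2 to 9 and 13 held 10 or more. The largest clusters held 18 regions each. They lay on chromosome 12 at 133327229 to 133398898 on the minus strand and on chromosome 2 at 54850616 to 54896846 on the plus strand. Clusters of 16 regions lay on chromosome 14 at 65233117 to 65266652 on the minus strand and on chromosome 21 at 47801609 to 47865682 on the plus strand.

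By chromosome, peaks were most numerous on chromosome 1 with 2013 ± 86.0 peaks per list (SD, n = 3 lists), chromosome 19 with 1704 ± 45.8 and chromosome 17 with 1269 ± 48.3. Chromosome 19 held 8.36 ± 0.0965% of a list's peaks, chromosome 13 held 1.72 ± 0.00491% and chromosome 21 held 1.33 ± 0.00568%. The share of regions found in all 3 lists varied little over the autosomes and X, from 55.0% on chromosome 13 (95% Wilson interval 50.4 to 59.5%) to 62.0% on chromosome 18 (56.9 to 66.9%), and these intervals overlapped.

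The position of peak edges was then compared between lists. In 15079 regions with 1 peak in each list, 10960 (72.7%) had the same start and the same end, to the base, in all 3 lists. Narrow regions had identical edges most often: 95.3% of those of up to 300 bp in MeRIP 1, against 43.8% of those over 1000 bp. The scores of these peaks differed between lists: of 8236 peaks with identical edges and scores below the ceiling in MeRIP 1 and MeRIP 2, 1 had the same score in both.

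Where only 1 edge was the same in a pair of lists, it was mostly the upstream edge. A mean of 2912 regions shared the upstream edge alone and 612 the downstream edge alone, an upstream share of 82.6 ± 0.742% (SD over the 3 pairs of lists, which share lists). Among regions over 1000 bp wide the upstream share was 92.4 ± 0.275%, or 2109 against 174 regions. The direction was the opposite among regions of up to 400 bp, where 79.3 regions shared the upstream edge alone and 204 the downstream edge alone, an upstream share of 28.0 ± 1.36%. All 3 pairs of lists lay on the same side, with 95% Wilson intervals that excluded 50% in each of these width classes.

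**Figure D3:**
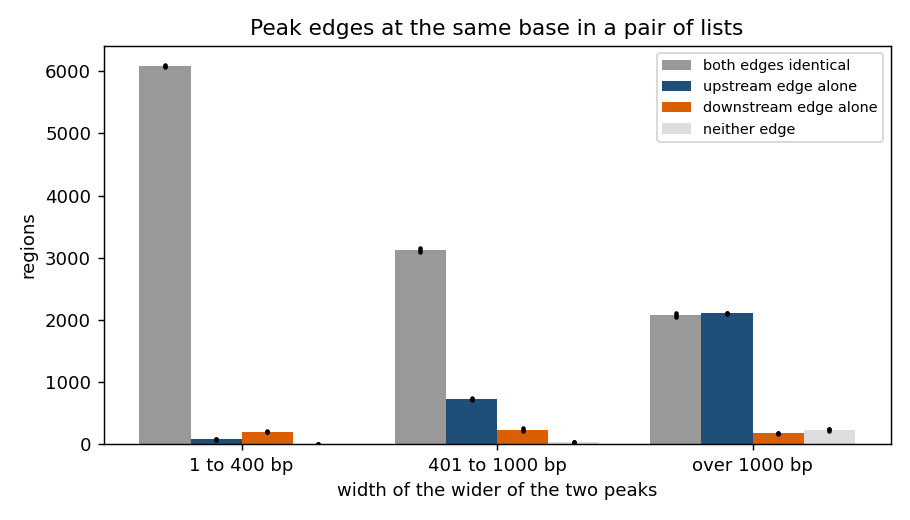
Mean number of regions (y axis) with both edges, the upstream edge alone, the downstream edge alone or neither edge at the same base in a pair of lists, by the width of the wider peak (x axis, bp). Points are the 3 pairs of lists, and in regions over 1000 bp the upstream edge alone (2109) outnumbers the downstream edge alone (174).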

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

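No paired analysis was possible because each deposited list already sets an IP against the input of its own repeat and holds no separate values for the libraries, so a block for the repeat could not be fitted. The number of regions in all 3 lists was 15265 in the main setting. It was 15283 with strand ignored and 15231 with chromosome Y left out, both chosen after seeing the data. Counted as peaks of MeRIP 1, the main setting gave 15371 in all 3 lists. That count was 15053 with a 50% reciprocal overlap and 15342 with 50% of the shorter peak. The number of regions fell to 10419 with peaks of at most 1000 bp, a setting that uses fewer peaks. All of these lay within 1.5 times the main count. The number ran from 16658 to 16947 when 1 repeat was left out and regions of both remaining lists were counted. It was 7993 with peaks at or above the median score of their own list and 7975 with peaks at or above the common median, since these settings use fewer peaks. Mean Spearman's rho was 0.86 with peaks at or above their list's median score, over a narrower range of scores, and 0.89 to 0.91 without 1 repeat. Identical edges in all 3 lists, whose alternatives were all chosen after seeing the data, were found in 5632 regions with peaks at or above their list's median score, again from fewer peaks, and in 12368 to 12495 regions without 1 repeat. The higher score of shared peaks, expected in part from the lowest score of 50 that all lists have, kept its direction and stayed past the threshold under every alternative run, with a smallest log2 difference of 2.43 for peaks of at most 1000 bp. The upstream share of single shared edges, with alternatives chosen after seeing the data, was 63.4% for peaks of at most 1000 bp and stayed above 50% under the alternatives run, apart from the class of up to 400 bp, where it was 28.0%. The share of ceiling peaks in all 3 lists was 91.0% for peaks of at most 1000 bp, also chosen after seeing the data. The alternatives for gene lists, transcript location, long exons and motifs were not run. Read depth is unknown, so a region missing from a list cannot be read as unmethylated there.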

Other observations

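Of the tests below, those on widths divisible by 3, on equal scores and on twin peaks of chromosomes X and Y, and the comparisons split at 1000 bp and with strong peaks in all 3 lists, were chosen after the values were seen; the predictions of the others were written before.

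Regions with a free downstream edge lay mostly at the downstream end of their clusters. In the 2544 clusters of 2 or more regions, 738 of 1019 regions that shared the upstream edge alone in all 3 lists were the last of their cluster along the strand (72.4%, 95% Wilson interval 69.6 to 75.1%), against 29.2% of the 5536 regions with both edges identical (28.1 to 30.5%). Among regions over 1000 bp wide the shares were 77.8% (74.6 to 80.6%) and 54.8% (51.2 to 58.2%), at median widths of 1974.5 and 1612 bp, so width was not matched exactly. A candidate explanation, as a hypothesis, is that these peaks start at the upstream edge of a transcript's last exon and end inside it, as is known of m6A near stop codons and in the 3' untranslated region. Neither exons nor stop codons were located here, and regions with neither edge shared were last in 70.2% of cases (60.3 to 78.5%, 94 regions).

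Regions of up to 1000 bp that shared the downstream edge alone lay more often at the upstream end. Of all 247 regions that shared the downstream edge alone, 136 were the first of their cluster (55.1%, 95% Wilson interval 48.8 to 61.1%), against 39.7% (38.5 to 41.0%) of those with both edges identical. At widths of up to 1000 bp the shares were 65.7% (58.2 to 72.5%) and 41.1% (39.8 to 42.5%), at median widths of 447 and 205 bp. Over 1000 bp they were 33.3% (24.0 to 44.1%, 81 regions) and 31.0% (27.9 to 34.4%), with overlapping intervals, and the wide regions that shared the downstream edge alone were last in 53.1% of cases (42.3 to 63.6%). Regions with neither edge shared, whose upstream edge is also free, were first in 19.1% (12.5 to 28.3%, 94 regions), but 84 of them were over 1000 bp and 10 were narrower, so width and type of edge were not separated. The narrower peaks may end at the downstream edge of a first exon, which was not tested against an annotation.

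The identical edges in all 3 lists are hard to place on peak calling alone. Edges 1 to 10 bp apart numbered 1.82 for each 100 identical edges over the 3 pairs of lists. Edges over 10 bp apart numbered 3668, 3618 and 3501 in the 3 pairs, and identical edges 26000, 26065 and 26197. Similar coverage was assumed to put many edges a few bases apart, and how far it would move an edge was not measured. The same IP and input reads behind both MeRIP 1 and MeRIP 2 are argued against by the scores. Of 8236 peaks with identical edges and scores below the ceiling, 0.0121% had equal scores in these lists. MeRIP 3 was not compared in this way, and a library shared between repeats with a different partner was not tested. Among identical regions of up to 300 bp, 39.5% had a width divisible by 3 (95% Wilson interval 38.2 to 40.9%), above the 33.3% of random widths, and coding exons are known to have such an excess. It was 36.3% in wider ones up to 1000 bp and 37.2% over 1000 bp, with intervals above 33.3%, so the excess was not particular to short regions, and 34.4% (33.0 to 35.9%) of regions with differing edges. This is consistent with peaks that the authors trimmed to annotated exons, in which case an edge marks an exon and not a methylated site, and overlap between lists is counted in whole exons; no biological explanation was tested.

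Strong peaks found in 1 list alone are the second pattern. Of 20979 peaks with a score of 1000 or more, 340 (1.62%) were in 1 list alone, 147 of them at the ceiling, such as chromosome 19 at 7963546 to 7966908 on the plus strand in MeRIP 1. MeRIP 1 had 161 of them, MeRIP 2 had 90 and MeRIP 3 had 89, which is 2.20% (1.89 to 2.57%), 1.35% (1.10 to 1.65%) and 1.27% (1.04 to 1.56%) of the strong peaks of each list, and 5.97%, 5.77% and 5.49% of the peaks found in that list alone. Chance loss near the threshold is argued against, since of 8528 regions with a highest score of 1000 or more, 0.633% (95% Wilson interval 0.486 to 0.825%) were in all 3 lists with a lowest score under 100, fewer than the 3.99% (3.59 to 4.42%) in 1 list alone, and a change of strand covered 4.12% of the 340 (2.47 to 6.79%). A same-strand peak of another list that the list itself lacked lay within 10 kb of 35.3% of them (30.4 to 40.5%), above the 20.7% (19.6 to 21.9%) of one-list peaks with scores under 200 and the 18.6% (18.1 to 19.2%) of strong peaks in all 3 lists. By list, chosen after the values were seen, it was 32.9%, 38.9% and 36.0% in MeRIP 1, 2 and 3, against 18.3%, 22.8% and 22.6% of one-list peaks with scores under 200. The comparisons with weak one-list peaks and with strong peaks in all 3 lists were not matched on width. The 340 peaks had a median width of 411.5 bp, against 948 bp for strong peaks in all 3 lists. Some of the 340 may be long peaks that were listed under different exons in different repeats. The rest stay open, including a true difference between repeats and the authors' choice of peaks.

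Some peaks on chromosome Y had a twin on chromosome X at a fixed offset. Of 126 peaks listed on chromosome Y over the 3 lists, 65 (51.6%, 95% Wilson interval 42.9 to 60.1%) had a peak of the same list, strand and width on chromosome X exactly 50 kb further along, an offset chosen because it was the commonest. Of the 42 twins below the ceiling 0% had equal scores (0 to 8.38%), which argues against each read being counted on both chromosomes. With 1 twin for each of the 21 separate regions of chromosome Y that they cover, scores differed by a median of 0.33 on the log2 scale, against 1.51 for peaks of the same list on other chromosomes with a width within 10% (the median over 100000 random draws, of which 1 was as small). Close but unequal scores are consistent with reads of a segment shared by both chromosomes being divided between the copies, an explanation found from these data, and reads were not available to test it. The other peaks listed on chromosome Y were not examined. For none of the 126 peaks does the listing alone show that the RNA was made from chromosome Y. Leaving out chromosome Y gave 15231 regions in all 3 lists.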
